A study of Escherichia coli with 43 samples.

How the data were processed

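RNA levels were measured on 43 2-colour arrays of 21 RNA samples in 11 groups. Per the labels, RNA was extracted with hot phenol-chloroform and a column and labelled by direct incorporation of labelled dCTP, with the RNA before treatment in Cy3 and the RNA after treatment in Cy5. The deposited single-channel files (86) hold scanner intensity values per spot, with local background values and no background subtraction or normalisation, per the file headers and column names. The headers give versions 5.5, 5.6.1 and 6.0.1 of the image software. The authors' processed table holds log10 ratios of Cy5 over Cy3, as read from the values of the deposited files. Its spots with a nonzero quality mark are absent, its arrays have medians between -0.021 and 0.02, and the method of background correction and normalisation is not given in the sources used here. The table holds between 6320 and 9334 spots per array. Across spots, its ratios correlated at 0.772 to 0.974 with ratios computed here by loess without background correction, which are not those of the main fits.

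Each array has 13440 spots in 32 blocks. Neighbouring spots were joined as 6720 features, since their levels correlated at 0.971 within such pairs and at 0.199 when the pairing was shifted by a spot. Of these features 5010 are in the authors' list of ratios and 1710 are not. Features in that list were kept when they stood above background (background median plus 2 SD) on at least 22 arrays, which left 4747, and the 4600 of these with a value in all 21 RNA samples were tested. Spots stood above background on 66.5% to 96.4% of an array in Cy3 and 44.7% to 95.3% in Cy5. Between 83 and 2415 spots of an array carry a manual quality mark. The number of RNA samples, rather than of arrays, limits the precision, since the arrays of an RNA sample were averaged.

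Samples were grouped by strain, treatment and medium as their labels give them. The labels do not state that Sample 1 and Sample 2 of a group are separate cultures, except that arcA sample 2 is a pool of 4 cultures, so the p-values measure the spread between these samples. The fit planned before the data were examined used limma with background correction by normexp (offset 50), loess within arrays, the mean of the arrays of an RNA sample, all 21 samples as labelled in a single fit, and Benjamini-Hochberg adjustment at 0.05. The comparisons, the rule for naming features and the first list of alternatives were also chosen before the data were examined. The 2 arrays with exchanged dyes were not used in this fit.

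After the data had been seen, 4 samples were listed by hand as of unsettled direction, from the correlations of their ratios: all 4 lie below -0.3 with the other sample of their group and with the mean of the remaining DeaNO samples. Which sample of such a pair was listed follows the majority of the DeaNO samples. The fits without them and with their sign turned, and the choice to open each comparison with the fit of the 17 others, came after the planned fit had been seen to give no call in 14 of 15 comparisons. Several further alternatives were also added then: the scan period as a covariate, a random block for the scan day, all printed features, 1 spot of each pair, and leaving out the array of the second platform. The sets of 50 features were defined from the data, for each group from the other DeaNO groups without the parent-strain DeaNO group, and tested with camera (preset correlation 0.01) and again with an estimated correlation. Sets of 25 and 100 features were tried as alternatives.

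Features were named by a rule: those with the highest and lowest log2 differences past the threshold whose samples all lie on 1 side of those of the other group, and, where none passed, those with the smallest p, given as not called. Because the files do not pair spots with gene names, at most 2 features that rose and 2 that fell are given per comparison. For the same reason the planned lists of genes, the regulon of each deleted regulator, the deleted genes and the genes chosen in advance were not analysed here. S5207 was named after its values had been seen.

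The fits were tested on simulated data with 100 changed features at each of 2 sizes. For the parent strain with DeaNO against control, 17 samples gave calls for 72% of the features changed by 1 log2 unit and 100% of those changed by 2, with 8 unchanged features called. With the change in all DeaNO groups and 4 samples of opposite sign, 21 samples gave 0% and 0%, and leaving these 4 out gave 58% and 100%. For the nsrR strain, with its 1 sample, 46% and 99% were called.

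The arrays were scanned on 21 days in 2 periods. The parent strain with DeaNO or serine hydroxamate and the arcA, iscR and norR strains lie in the earlier period, the argR, metJ, nsrR and nsrR_hmpA strains in the later, and the control and methionine groups in both. The scan images of all norR arrays and of serine hydroxamate sample 2 have another form of name than those of all other arrays. The work used R 4.3.3, limma 3.58.1, statmod 1.5.0, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.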

Results

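The series measured transcript levels in Escherichia coli on 2-colour arrays, in the parent strain BW25113 and in strains derived from it that lack a regulator gene. Cells grew with air in MOPS minimal medium with 0.5% glucose and received DeaNO, a compound that releases nitric oxide (NO) in water, at 8 µM for 5 minutes. Per the labels, Cy3 held RNA taken before the addition and Cy5 RNA taken 5 minutes after it on all arrays but 2, which had the dyes exchanged, so that each ratio is the change of a transcript over these 5 minutes. The series' title and design text name the NO response network as the subject, inferred by network analysis and followed up with deletion strains.

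There were 43 arrays of 21 RNA samples in 11 groups. The parent strain was treated with degraded DeaNO as the control, with DeaNO, with DeaNO in medium holding 50 µg/mL methionine, and with serine hydroxamate at 1 mg/mL, an analogue of serine that inhibits the charging of its tRNA. The deletion strains, all treated with DeaNO, lacked argR (the arginine repressor), arcA (the response regulator of the Arc system for respiratory control), iscR (a regulator of iron-sulphur cluster assembly), metJ (the methionine repressor), norR (an NO-sensing activator), nsrR (an NO-sensitive repressor), or nsrR together with hmpA (flavohaemoglobin, which consumes NO). Each group had 2 RNA samples, except the nsrR strain with 1, and each RNA sample was on 2 arrays, except 1 array for the 2nd nsrR_hmpA sample and 2 additional arrays with exchanged dyes for parent-strain DeaNO sample 1. The median Cy3 signal of an array lay between 476.7 and 3578, the median Cy5 signal between 629 and 2631, and between 44.7% and 95.3% of the spots stood above background in Cy5 on an array. The small number of samples limits the precision of every value.

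The files do not pair spots with gene names, so features carry an S and the number of the first of their 2 neighbouring spots, and at most 2 features in each direction are given per comparison. No deleted gene or known regulon could be read out. Of 6720 such spot pairs, 4600 were tested.

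The direction of 4 RNA samples was not settled. Sample 1 of argR and samples 2 of metJ, norR and nsrR_hmpA (7 arrays) carry the same dye labels as the other samples, yet their ratios correlated across features at -0.36, -0.60, -0.49 and -0.34 with the other sample of the same strain and treatment. With the mean of the remaining DeaNO samples their correlations were -0.43, -0.65, -0.47 and -0.52, and with each other they lay between 0.431 and 0.632. The count of each comparison is therefore given in 3 ways: with all 21 samples as labelled, which was the fit planned before the data were examined, with the sign of these 4 samples turned, and with the 4 left out. The planned fit called no feature in 14 of 15 comparisons. The decision to open each comparison with the 17 remaining samples was made after that result had been seen. In those 17 samples the argR, metJ, norR and nsrR_hmpA strains have 1 sample each, and nsrR has 1 by design. These lone samples have no spread of their own and are assumed to vary like the other groups. The spread of this fit comes only from groups with 2 remaining samples. The disagreement within the 4 strains that lost a sample therefore does not enter their SEs and p-values, which may be too small. Among 4600 features, chance alone gives about 230 with an unadjusted p under 0.05.

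DeaNO changed a limited set of features strongly in the parent strain within 5 minutes. Against the degraded compound, 61 features were higher and 63 lower in the 17 samples. S7687 changed by 4.21 ± 0.43 (SD, n = 2) log2 units with DeaNO and by -0.34 ± 0.01 (SD, n = 2) in the control. The difference was 4.54 (SE 0.67, adjusted p = 0.00244). S4955 differed by 4.05 (SE 0.37, adjusted p = 6.34e-05). S1047 fell by 2.90 (SE 0.45, adjusted p = 0.00289) and S1015 fell by 2.84 (SE 0.42, adjusted p = 0.00244) relative to the control. These are limma values with Benjamini-Hochberg adjustment at 0.05. As labelled, all 21 samples gave 0 features by limma (360 at an unadjusted p under 0.05), while turning the sign of the 4 samples gave 44 higher and 27 lower. In all 3 fits the 4 differences have the same sizes by construction, since none of these 4 samples belongs to either group. Only their SEs and p-values could move. The count in the 17 samples depended on single samples and on the scan period: it was 18 without control sample 2 (which leaves only arrays of the period in which both parent-strain DeaNO samples were scanned), 210 without control sample 1, 41 without DeaNO sample 2, and 56 with the period as a covariate. The balance of the directions moved with the scaling, from 61 higher and 63 lower to 63 and 33 with a loess curve per print block and to 80 and 51 with median centring.

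Tested against 0, the ratios of the parent strain with DeaNO gave 345 features higher and 308 lower after treatment than before in the 17 samples. The background measured in the same way with degraded DeaNO was 0 higher and 6 lower, among them S4321 at -1.04 (SE 0.19, adjusted p = 0.0494). A dye effect stays in both counts, since all these arrays have the treated RNA in Cy5. It may not cancel in the comparisons against the control either. A dye effect measured on parent-strain DeaNO sample 1 had coefficients of 0.175 to 0.404 on the control arrays. They were -0.004 and 0.028 on those of parent-strain DeaNO sample 2 and -0.106 to 0.077 with serine hydroxamate. Its share in the counts against the control was not tested. As labelled the counts by limma were 0 and 0 (964 and 369 at an unadjusted p under 0.05), and with the 4 samples turned they were 279 higher with 214 lower for DeaNO and 0 for the control (370 at an unadjusted p under 0.05). The planned DeaNO count was 36 without DeaNO sample 2, and the planned control count 17 without control sample 1. In the 17 samples, the DeaNO count was 327 without sample 1 and 274 without sample 2, and its balance was 412 to 242 with a loess curve per print block and 349 to 193 with median centring. The control count was 66 without control sample 1, 0 without control sample 2 and 0 with the scan period as a covariate.

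**Figure D1:**
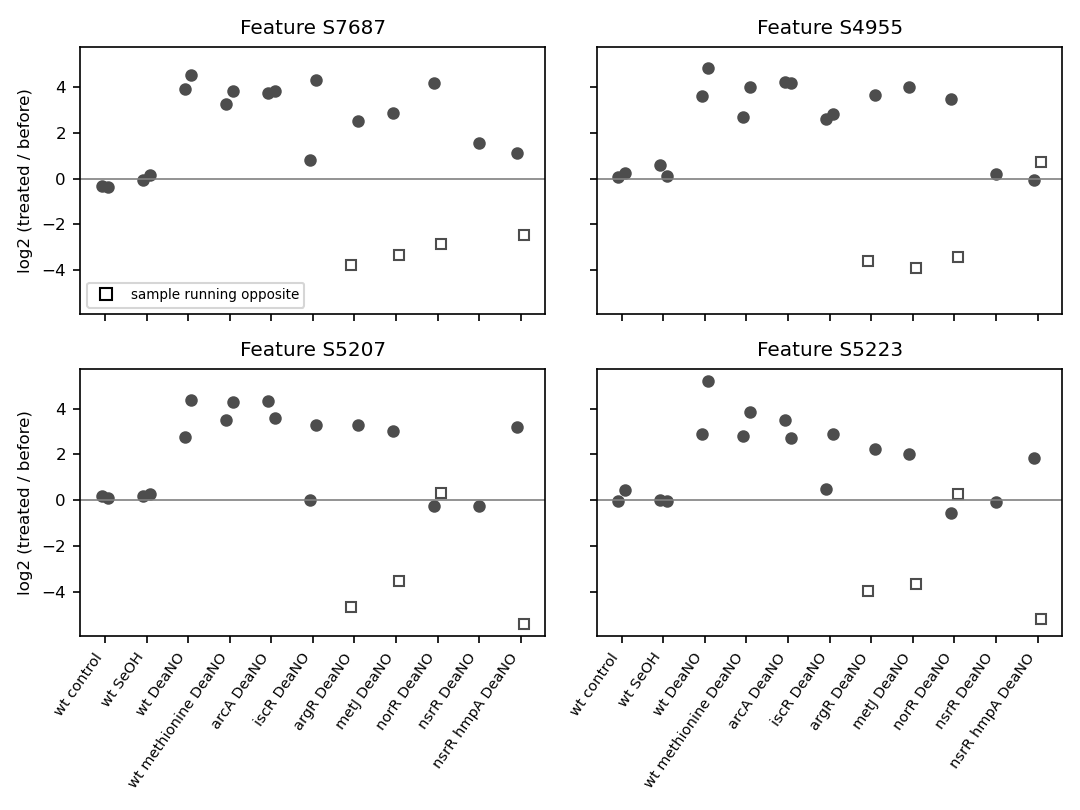
Log2 ratio of RNA after over before treatment for 4 features in each RNA sample (points), by group on the horizontal axis, with the 4 samples of unsettled direction as open squares. S7687 and S4955 lie near 0 in both control samples and between 3.62 and 4.81 in the parent-strain DeaNO samples, and S5207 and S5223 lie between -0.56 and 0.30 in the norR samples.

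Serine hydroxamate changed mostly features that fell. Against degraded DeaNO, 27 features were higher and 105 lower in the 17 samples. S4901 was higher by 2.04 (SE 0.35, adjusted p = 0.00639), while S321 fell by 3.15 (SE 0.53, adjusted p = 0.00538) and S4455 fell by 2.96 (SE 0.47, adjusted p = 0.00538). In limma, the planned fit gave 0 features (424 at an unadjusted p under 0.05) and the turned fit 20 higher and 63 lower. The count was 6 without control sample 2, which leaves the scan period of the serine hydroxamate samples, 12 without serine hydroxamate sample 1, 58 without sample 2 and 65 with the period as a covariate.

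The 2 treatments of the parent strain differed from each other. Relative to DeaNO, 16 features were higher and 74 lower with serine hydroxamate in the 17 samples. S5681 was higher by 2.13 (SE 0.34, adjusted p = 0.00301). S7687 and S5223 were lower by 4.16 (SE 0.67, adjusted p = 0.0034) and 4.07 (SE 0.68, adjusted p = 0.00404). With serine hydroxamate their mean ratios were 0.048 and -0.01, against 4.209 and 4.063 with DeaNO, so that they lacked the rise and did not fall. The planned fit called 0 higher and 3 lower, and the turned fit 9 higher and 52 lower. The scan images of serine hydroxamate sample 2 have another form of name than those of the other samples compared here. Both treatments lie in the same scan period, and the count was 17 without serine hydroxamate sample 1, 43 without its sample 2 and 49 without DeaNO sample 1.

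Some features were called with both treatments. In the 17 samples, 21 features were lower in both comparisons against the control, 7 were higher in both and 4 were called in opposite directions, where independent lists of these lengths would share 1.44, 0.358 and 1.76 and 100 simulated pairs of unchanged groups against the same controls shared on average 0.02, 0 and 0. The first values leave out the shared controls and the second the effects of the treatments, which lengthen the lists, so part of the excess over either may come from the shared controls. Across features, the log2 differences of the 2 comparisons correlated at 0.564, against a mean of 0.499 and a highest value of 0.532 in 100 simulated pairs of unchanged groups that shared the controls. Their covariance was 0.0857, against a simulated mean of 0.0235. Simulated features varied independently of each other, each with the same spread in every sample. In the data, spots 32 apart in number correlated at 0.342, and the control samples came from 2 scan periods. Values above the simulated range therefore do not by themselves show a shared response. With a different control sample for each treatment, the correlation was 0.336 and 0.26 and the covariance 0.0595 and 0.0477, and no feature was called lower in both and at most 1 higher in both or in opposite directions. These last fits have 1 control sample per treatment, and features are not independent replicates. As labelled, the lists shared 0, 0 and 0 features, since each list was empty, and with the 4 samples turned they shared 6 lower, 5 higher and 1 opposite.

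To compare strains as a whole, each RNA sample was read over the 50 features most induced and the 50 most repressed by DeaNO in the other DeaNO groups among the 17 samples. The parent-strain DeaNO group never entered the choice of these sets, which were defined after the data had been seen. The median log2 ratio over the induced set was 1.23 and 1.30 in the parent-strain samples, 0.19 and 0.01 in the control samples, and 0.30 and 0.26 with serine hydroxamate. Over the repressed set it was -0.86 and -1.34 with DeaNO, -0.03 and 0.24 in the control, and -0.98 and -0.81 with serine hydroxamate. The induced set differed between DeaNO and control by a mean of 1.39 log2 units (camera, adjusted p = 3.57e-42 with a preset correlation of 0.01), with 33 of its 50 features called higher, and the repressed set by -1.25 (adjusted p = 8.77e-38), with 25 called lower. Of 26 such tests, 6 remained under 0.05 with an estimated correlation: the induced set in DeaNO against control, in iscR, nsrR and serine hydroxamate against parent-strain DeaNO and in nsrR_hmpA against nsrR, and the set most induced by serine hydroxamate in DeaNO against control. The repressed set in DeaNO against control had an adjusted p = 0.0518 with an estimated correlation. With serine hydroxamate against control, the repressed set lay at -1.15, with 23 of 50 features called lower and an adjusted p = 0.0567 with an estimated correlation, and the induced set at 0.152 (adjusted p = 0.424 with an estimated correlation) with 4 features called higher and 4 lower. The induced set lay lower with serine hydroxamate than with DeaNO by a mean of -1.23 (adjusted p = 0.0082 with an estimated correlation). The set most induced by serine hydroxamate was higher with DeaNO than in the control by 0.499 (adjusted p = 0.00585 with an estimated correlation), and the set it most repressed lay at -0.821 (adjusted p = 0.138 with an estimated correlation).

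**Figure D2:**
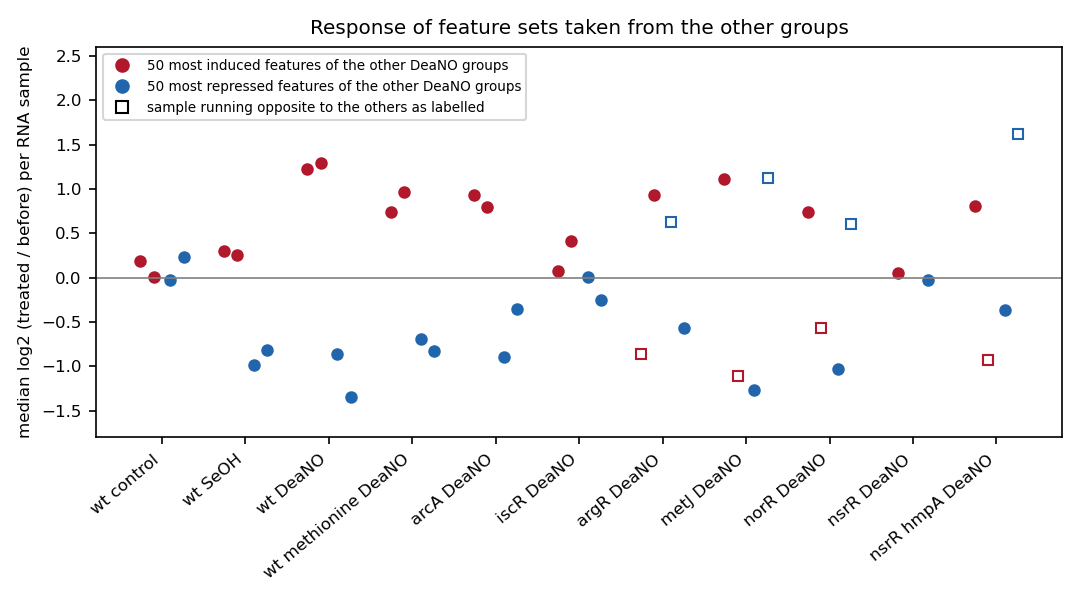
Median log2 ratio of RNA after over before treatment in each RNA sample (points) over the 50 features most induced (red) and the 50 most repressed (blue) in the other DeaNO groups, with the 4 samples of unsettled direction as open squares. The parent-strain DeaNO samples sit at 1.23 and 1.30 over the induced set, the nsrR sample at 0.05, and the open squares have the signs of both sets exchanged.

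Averaged over the 9 DeaNO groups with equal weight, 19 features were higher and 28 lower than in the control in the 17 samples. S7687 was higher by 3.26 (SE 0.51, adjusted p = 0.00928) and S3579 by 1.95 (SE 0.27, adjusted p = 0.00367), while S4455 and S1015 each fell by 1.75 (SE 0.36 and 0.33, adjusted p = 0.0329 and 0.0289). By limma, the planned fit gave 0 features (222 at an unadjusted p under 0.05) and the turned fit 14 higher and 5 lower. The count was 1 without control sample 2, 117 without control sample 1, 91 without arcA sample 2, 78 without parent-strain DeaNO sample 1, 24 without methionine sample 2 and 57 with the scan period as a covariate, and its balance was 32 higher to 31 lower with median centring.

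The iscR strain responded less to DeaNO than the parent strain. Over the induced set its samples had medians of 0.08 and 0.41, and the set lay below the parent strain by a mean of -1.06 (adjusted p = 0.00585 with an estimated correlation), with 15 of its 50 features called lower and none called higher. The repressed set lay at 0.928 (adjusted p = 0.0647 with an estimated correlation). In all, 6 features were higher and 17 lower than in the parent strain in the 17 samples. S4795 was lower by 2.17 (SE 0.27, adjusted p = 0.00147) and S4623 by 2.16 (SE 0.24, adjusted p = 0.000946) relative to the parent. Their mean ratios in iscR were 0.036 and -0.108. The mean level of S4623 over both channels lay at least 3.26 log2 units lower in the iscR samples than in every other sample. S5357 was higher by 1.74 (SE 0.34, adjusted p = 0.0246) and S6975 by 1.56 (SE 0.30, adjusted p = 0.0258). The 2 iscR samples differed, with S7687 at 0.81 and 4.32, and the ratios of sample 1 spread over features with an SD of only 0.179. By limma, the planned fit gave 0 features (265 at an unadjusted p under 0.05) and the turned fit 3 higher and 12 lower. Both strains lie in the earlier scan period. The count was 6 without iscR sample 1, 80 without parent sample 1 and 12 without parent sample 2, and the authors' processed values gave 1 higher and 12 lower.

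The nsrR strain, with 1 RNA sample, showed little of the parent response. Its medians over the induced and repressed sets were 0.05 and -0.02, and the induced set lay below the parent strain by a mean of -1.40 (adjusted p = 0.00585 with an estimated correlation), with 20 of 50 features called lower and none called higher. The repressed set lay at 1.10 (adjusted p = 0.0647 with an estimated correlation). S7687 still rose, by 1.56. Across features, the ratios of this sample had an SD of 0.173, the smallest of the DeaNO samples, and correlated at 0.169 with the mean of the other settled DeaNO samples. In the 17 samples 12 features were higher and 25 lower than in the parent strain. S5223 was lower by 4.13 (SE 0.83, adjusted p = 0.0309) and S4955 by 3.99 (SE 0.46, adjusted p = 0.00114) relative to the parent. Their ratios in nsrR were -0.066 and 0.224. S1047 and S1015 were higher than in the parent by 2.54 (SE 0.55) and 2.39 (SE 0.52), both with an adjusted p = 0.0443. The Cy3 level of S4955 before treatment was 12.88 log2 units in nsrR and between 9.77 and 10.71 in the 11 other DeaNO samples of settled direction outside nsrR_hmpA. By limma, the planned fit gave 0 features (197 at an unadjusted p under 0.05) and the turned fit 4 higher and 12 lower. All nsrR arrays were scanned in the later of the 2 periods and all parent-strain DeaNO arrays in the earlier, so that no value within a period exists: with the period as a covariate the count was 0 higher and 3 lower, S4955 was still called while S1047, S1015 and S5223 were not, and the induced set lay at -1.52. The count was 66 without parent sample 1 and 16 without parent sample 2, and its balance was 2 higher to 24 lower with median centring and 1 to 17 with the authors' processed values.

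In the nsrR_hmpA strain the ratio of S4955 was -0.07 in sample 1. Relative to the parent, S4955 was lower by 4.28 (SE 0.46) in the 17 samples, a difference that was called. The induced set had a median of 0.81 in sample 1 and lay at -0.595 relative to the parent (adjusted p = 0.0647 with an estimated correlation), and the repressed set at 0.668 (adjusted p = 0.165 with an estimated correlation). Compared with nsrR, which sets 1 RNA sample against 1 in this fit, the induced set was higher by 0.772 (adjusted p = 0.0111 with an estimated correlation), the repressed set lay at -0.439 (adjusted p = 0.209 with an estimated correlation), and S2105 was the only feature called, higher by 2.09 (SE 0.33, adjusted p = 0.0482). The direction of sample 2 moved these values. Against the parent, the induced and repressed sets lay at -1.55 and 1.7 as labelled and at -0.505 and 0.108 with the signs turned, the last not under 0.05 even with the preset correlation. Against nsrR they lay at -0.175 and 0.618 as labelled and at 0.854 and -1.02 turned, and S2105 was not called in either of these fits. By limma, the planned fit gave 0 features against the parent (829 at an unadjusted p under 0.05) and 0 against nsrR (81). Without nsrR_hmpA sample 1, which leaves the sample of unsettled direction as labelled, it gave 426 and 3. By limma, the turned fit gave 1 higher and 3 lower against the parent and 0 against nsrR (388). The count of the 17 samples against the parent was 3 without parent sample 1 and 2 without parent sample 2, and with the period as a covariate it was 1, and 0 against nsrR, where S2105 was at 2.09.

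**Figure D3:**
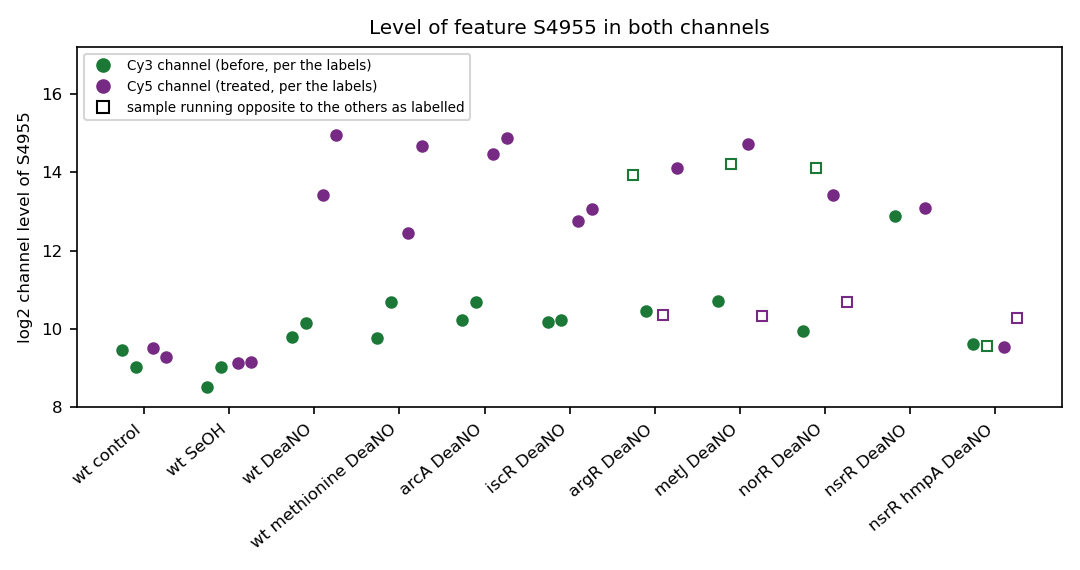
Log2 level of feature S4955 in the Cy3 channel (green, before treatment per the labels) and the Cy5 channel (purple, after treatment) of each RNA sample, by group, with the 4 samples of unsettled direction as open squares. Cy3 stands at 12.88 in nsrR, above the range of 9.77 to 10.71 of the 11 other settled DeaNO samples, and both channels of both nsrR_hmpA samples lie between 9.54 and 10.27.

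The norR strain gave no called feature against the parent in the 17 samples (limma, 97 at an unadjusted p under 0.05). The smallest p values belonged to S5223 at -4.62 (SE 0.83, adjusted p = 0.223) and to S5239 and S5207 at -1.22 (SE 0.27) and -3.83 (SE 0.86), both with an adjusted p = 0.69. The ratios of S5207 and S5223 in norR sample 1 were -0.26 and -0.56, against 3.58 ± 1.16 and 4.06 ± 1.63 (SD, n = 2) in the parent strain. Before treatment, however, the Cy3 levels of the pair in norR sample 1 were 11.46 and 10.08, above the 12 other settled DeaNO samples (7.84 to 10.56 and 7.4 to 9.95), and in sample 2 they were 10.55 and 8.75. Low ratios of this pair were also seen in nsrR (-0.23 and -0.07) and in iscR sample 1 (0.03 and 0.49), though not in iscR sample 2 (3.273 and 2.909). Over the sets, norR lay at -0.492 for the induced features (adjusted p = 0.0518 with an estimated correlation) and at -0.019 for the repressed (adjusted p = 0.923 with an estimated correlation). As labelled these were -1.36 and 0.89, and with the signs turned -0.566 and 0.206. The planned fit also gave 0 features (201 at an unadjusted p under 0.05), as did the turned fit (268). Both strains lie in the earlier scan period but differ in scanning. All norR arrays have software version 5.5, another form of image name and median Cy3 backgrounds of 208 to 496. The parent-strain DeaNO arrays of the fit have version 5.6.1 and backgrounds of 10 to 43. Deletion of norR cannot be told apart from these differences.

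Few features separated the argR and arcA strains from the parent. In argR, 3 features were higher and none lower in the 17 samples (limma, 327 at an unadjusted p under 0.05), with S8101 at 2.13 (SE 0.30) and S4563 at 1.90 (SE 0.29), both with an adjusted p = 0.014. In arcA, 3 were lower and none higher (439 at an unadjusted p under 0.05), with S1219 at -2.24 (SE 0.38) and S1203 at -2.15 (SE 0.34), both with an adjusted p = 0.0444. The induced set lay at -0.283 in argR and -0.318 in arcA and the repressed set at 0.581 and 0.378, with adjusted p = 0.209, 0.165, 0.248 and 0.26 with an estimated correlation. In argR they lay at -1.46 and 1.19 as labelled and at -0.304 and 0.538 with the signs turned. The planned fit gave 0 features by limma in argR (586 at an unadjusted p under 0.05) and 0 in arcA (271), and the turned fit 7 higher and 1 lower in argR and 0 in arcA (356). The argR count was 7 without parent sample 1, 0 without parent sample 2 and 0 with the scan period as a covariate, the periods of argR and parent being separate. The arcA count was 18 without arcA sample 1, 0 without its sample 2, 1 without parent sample 1, 0 without parent sample 2 and 5 with the period as a covariate.

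The metJ strain and methionine in the medium gave no called feature in the 17 samples with arrays averaged. A fit of single arrays, with the RNA sample as a random block, gave 83 for methionine and also called features for metJ. In that fit the arrays of metJ all come from 1 RNA sample, so its calls rest on repeated arrays of that RNA. In metJ against the parent, limma gave 0 features with arrays averaged (697 at an unadjusted p under 0.05), with S7085 at -1.66 (SE 0.28, adjusted p = 0.0559) and S2665 at 1.34 (SE 0.24, adjusted p = 0.0586) among the smallest p values. With methionine it also gave 0 (724), with S5227 at -1.41 (SE 0.22, adjusted p = 0.0539) and S1841 at 1.16 (SE 0.20, adjusted p = 0.0606). The induced and repressed sets lay at -0.166 and -0.124 in metJ and at -0.339 and 0.213 with methionine (adjusted p = 0.768, 0.807, 0.165 and 0.768 with an estimated correlation). As labelled, the sets lay at -1.5 and 1.08 in metJ, both under 0.05 with the preset correlation, and with the signs turned at -0.152 and -0.0254, neither under it. The planned fit gave 0 in both (663 and 526 at an unadjusted p under 0.05), and the turned fit 1 higher and 1 lower in metJ and 0 with methionine (608). The metJ count was 5 without parent sample 1 and 34 without parent sample 2, and the methionine count was 1 and 8 without these and 10 without methionine sample 1. With the scan period as a covariate both were 0, and metJ and parent share no period.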

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

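The fit of 17 samples, the sets of features, the test of the norR deletion itself and the comparison of scan periods for S4955 were chosen after the results had been seen. The other tests of the 3 patterns below had their bounds written beforehand, apart from values given as seen afterwards. The set differences listed here were also limited afterwards to those under 0.05 with an estimated correlation.

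Differences between groups were tested directly against parent-strain DeaNO in the 17 samples. Features called numbered 3 for argR, 3 for arcA, 23 for iscR, 37 for nsrR, 1 for nsrR_hmpA and 90 for serine hydroxamate. Between nsrR_hmpA and nsrR 1 feature was called. The DeaNO-induced set differed by -1.06 log2 units in iscR, -1.40 in nsrR and -1.23 with serine hydroxamate against the parent, and by 0.772 between nsrR_hmpA and nsrR. The 2 results between nsrR_hmpA and nsrR compare 1 RNA sample with 1, and as labelled the set differed by -0.175 and the feature was not called. Among 1613 features that the authors' table leaves out, tested only in the alternative with all printed features, 77 were called in the parent strain with DeaNO against before, where the control gave 2. Against the control itself, 2 of these features were called with DeaNO and 2 with serine hydroxamate.

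In 4 RNA samples the ratios ran opposite to those of the other DeaNO samples, with dye labels like theirs. The tables argue against an opposite response of treated cells that started from the level of the other samples. The Cy3 level of the induced features, which the labels place before treatment, lay above that of the other DeaNO samples in all 4. It did so by 1.09 to 1.75 log2 units, while in the settled samples the difference lay between -0.744 and 0.398. Cells that started high and then fell would show the same Cy3 level. The Cy5 level of these features differed by -0.562, -0.354, -0.52 and -0.029, and what exchanged RNAs would give there was not computed for the set. For S4955, argR sample 1, metJ sample 2 and norR sample 2 had Cy3 levels of 13.94, 14.22 and 14.11. Their Cy5 levels were 10.36, 10.32 and 10.7. In 11 settled DeaNO samples Cy5 lay between 12.44 and 14.96 and Cy3 between 9.77 and 10.71. Exchanged RNAs would give such levels of S4955, as would cells that started high and fell. In nsrR_hmpA sample 2, S4955 lay at 9.56 and 10.27 and does not bear on this. A dye effect measured on parent-strain DeaNO sample 1 was above 0 on 7 of the 7 arrays, which meets the bound written against exchanged channel files, but that bound assumed a value above 0 on normally labelled arrays, and only 20 of the 32 others had one (metJ sample 1 lay at -0.241 and -0.4), so its sign does not settle the point. An exchange of dyes, tubes or channel files stays open, as do cultures in which these features were already high before treatment and fell after it, which was not tested.

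S5207 and S5223 rose in the parent strain with DeaNO and stayed within 0.56 log2 units of 0 in both norR samples, a test written after the values had been seen. The tables argue against unreadable spots, since 1 of the 16 spots on the norR arrays carries the manual mark. A weaker response of the norR samples as a whole cannot be told apart: the median over the other induced features was 0.702 of the parent response in sample 1 (bootstrap 95% interval 0.528 to 0.807), which passes its bound of 0.7 by less than that spread, and 0.512 (0.351 to 0.699) in sample 2 with its sign turned. Each of these intervals covers 1 RNA sample and holds no spread between samples. Seen afterwards, the ratios of the pair in sample 1 lay at most at -2.77 from the scaled parent response, while the lowest of the other 48 features lay at -0.656. The pair was picked for low values in norR, and its parent responses (3.58 and 4.06) exceed the median of the others (1.14). Features with a small parent response cannot lie that far below, so these values alone do not show a loss particular to the pair. S7687 and S4955 had parent responses as large (4.209 and 4.216) and could have lain as far below. Their ratios were 4.156 and 3.468 in norR sample 1, and -2.835 and -3.414 in sample 2 as labelled. These features thus kept a strong change on the arrays where the pair stayed near 0. Deletion of norR may be the cause, as may a high level before treatment (Cy3 11.46 and 10.08 in norR sample 1, and 10.56 and 9.95 in nsrR), which was not tested. A difference in scanning between the norR and parent arrays was not tested either. In nsrR and iscR sample 1 a rise of the pair was also lacking. Over the induced set these samples had medians of only 0.052 and 0.078, against 0.738 in norR sample 1. In iscR sample 2 the pair rose by 3.273 and 2.909.

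S4955 rose in the parent strain and not in nsrR or nsrR_hmpA. Saturated or marked spots are argued against, with 0 of 10 spots so. In nsrR the Cy3 level before treatment lay 2.17 log2 units above the highest of the other settled DeaNO samples, consistent with a transcript already high. In nsrR_hmpA the highest level lay -2.18 from the lowest treated level of those samples, as for a transcript that is absent or not induced there. Its levels of 9.54 to 10.27 lay above those in the control (9.02 to 9.52) and with serine hydroxamate (8.53 to 9.16). Absence is therefore not shown. A difference between scan periods is argued against as the whole cause, since S4955 rose by 3.66 in argR sample 2, 4.02 in metJ sample 1 and 3.99 in methionine sample 2, all of the later period like nsrR and nsrR_hmpA, and was still called in both strains with the period as a covariate; an effect of the deletions stays open, and the files do not name the feature.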

How the results depend on the processing

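Turning the sign of the 4 samples, leaving them out, the scan period or day, all printed features, 1 spot of each pair, the array of the second platform and every alternative on the 17 samples were chosen after the data had been seen; the rest was planned. Of 514 counts under alternatives, 348 lay within 1.5 times the count reported and 166 did not. Of 768 values of named features, 557 kept their direction and side of the threshold, 172 lost the call, 38 gained it and 1 reversed. Of 260 set values, 222 kept both, 19 lost the call, 9 gained it and 10 reversed. Except where a cause is stated, the cause was not tested. Counts are features called by limma, and the comparisons with strains and with methionine are against parent-strain DeaNO. The fit of single arrays takes each array as a unit, with the RNA sample as a random block. Repeated arrays of the same RNA therefore add to its counts without being further samples.

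With the sign of the 4 samples turned in the planned fit, the counts were 71 for DeaNO against control, 19 for the mean of the DeaNO groups, 493 for DeaNO against before, 83 for serine hydroxamate against control and 61 against DeaNO. For the strains they were 8 for argR, 15 for iscR, 2 for metJ, 16 for nsrR and 4 for nsrR_hmpA. With the 4 left out, they were 124, 47, 653, 132 and 90 in the same order, 6 for the control against before, 3 for argR, 3 for arcA, 23 for iscR, 37 for nsrR, 1 for nsrR_hmpA and 1 for nsrR_hmpA against nsrR. Simulated data with 4 samples of opposite sign lost all calls in the same way. Fitting only the 2 groups compared, which leaves these samples out as well, gave 78 for DeaNO and 137 for serine hydroxamate against control.

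Other settings of the planned fit moved DeaNO against before to 67 without background correction, 11 with a loess curve per print block, 279 in the fit of single arrays, 13 with 1 spot of each pair and 38 without the array of the second platform. Serine hydroxamate against DeaNO, 3 as planned, was 1 with the swapped arrays turned and averaged in, 39 in the fit of single arrays, 1 with the authors' values and 1 with 1 spot of each pair. The fit of single arrays also gave 4 for the control against before, 30 for serine hydroxamate against control, 10 for argR, 48 for metJ and 88 for nsrR_hmpA. The authors' values gave 1 for the control against before.

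With the sample number of the labels as a replicate block, the planned fit gave 105 for DeaNO against before and 1 for serine hydroxamate against control. In the 17 samples this block gave 0 for the control against before and 0 for nsrR_hmpA against nsrR. The sample numbers were not taken as a pairing: the difference of sample 1 and sample 2 correlated across features above 0.1 in 17 of 45 pairs of groups, between -0.625 and 0.754, and in 6 of 15 pairs of groups without opposite samples, between -0.276 and 0.201.

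In the 17 samples, the fit without background correction gave 0 for the control against before, 3 for metJ and 2 for methionine. A loess curve per print block gave 12 for the mean of the DeaNO groups, 0 for the control against before, 0 for argR, 1 for metJ and 19 for nsrR. Median centring gave 1 for metJ and 1 for methionine. Without the filter on dim features the control against before gave 2 and nsrR_hmpA against nsrR 0. All printed features gave 0 for arcA, 17 for metJ, 3 for nsrR_hmpA, 0 for nsrR_hmpA against nsrR and 3 for methionine.

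The swapped arrays, averaged in, gave 85 for the mean of the DeaNO groups, 5 for argR, 1 for arcA, 6 for metJ, 2 for nsrR_hmpA, 2 for nsrR_hmpA against nsrR and 4 for methionine. In the fit of single arrays, DeaNO against control was 206, the mean of the DeaNO groups 129, the control against before 18, and serine hydroxamate 219 against control and 141 against DeaNO. That fit gave 7 for argR, 23 for arcA, 84 for iscR, 86 for metJ, 2 for norR, 73 for nsrR, 3 for nsrR_hmpA and 83 for methionine. The authors' values gave 26 for the mean of the DeaNO groups, 1 for the control against before, 52 for serine hydroxamate against DeaNO, 0 for argR, 0 for arcA and 13 for iscR. They gave 18 for nsrR, 0 for nsrR_hmpA, 0 for nsrR_hmpA against nsrR and 3 for methionine.

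The scan period as a covariate gave 56 for DeaNO and 65 for serine hydroxamate against control, 0 for the control against before, 0 for argR, 5 for arcA, 3 for nsrR and 0 for nsrR_hmpA against nsrR. The scan day as a random block gave 197 for DeaNO against control. A single spot of each pair gave 29 for DeaNO against control, 5 for the mean of the DeaNO groups, 339 for DeaNO against before, 0 for the control against before, and 13 and 27 for serine hydroxamate against control and DeaNO. It gave 0 for argR, 0 for arcA, 8 for iscR, 3 for nsrR, 2 for nsrR_hmpA and 0 for nsrR_hmpA against nsrR. Without the array of the second platform, the control against before was 1, arcA 5, metJ 3 and methionine 3. Fitting only the 2 groups gave 78 for DeaNO against control, and asking for at least 2-fold gave 83 for serine hydroxamate against control, which removes features by construction.

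Leaving out 1 sample at a time in the planned fit gave 0 to 2 for the mean of the DeaNO groups and for argR, 0 to 1 for arcA, for DeaNO and serine hydroxamate against control and for serine hydroxamate against DeaNO, and 0 to 17 for the control against before. It gave 0 to 36 for DeaNO against before, 0 to 3 for nsrR_hmpA against nsrR, 0 to 426 for nsrR_hmpA against the parent and 0 throughout for iscR, metJ, norR, nsrR and methionine. In the 17 samples it gave 18 to 210 for DeaNO and 6 to 172 for serine hydroxamate against control, 17 to 110 for serine hydroxamate against DeaNO, 1 to 117 for the mean of the DeaNO groups and 274 to 327 for DeaNO against before. For the control against before it gave 0 to 66, for argR 0 to 7, for arcA 0 to 18, for iscR 6 to 80, for metJ 5 to 34, for norR 0 to 1, for nsrR 16 to 66, for nsrR_hmpA 2 to 3 and for methionine 0 to 10. A lone sample left in a group is assumed to vary like the other groups.

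The values that reversed were mostly small. The DeaNO-repressed set in norR, at -0.019, was 0.890 as labelled, 0.206 with the signs turned, 0.0102 without background correction, 0.0972 with the authors' values and 0.0431 with sets of 25 features. In metJ it was 1.08 as labelled and 0.0418 with sets of 25. Between nsrR_hmpA and nsrR, as labelled, the induced set was -0.175, the repressed set 0.618 and S2105 -0.055. The induced set with serine hydroxamate against control was -0.0744 with sets of 25.

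The array layout as a covariate was not run, since the arrays share a single layout, nor were the alternatives for lists of genes, since the files do not pair spots with names. Of the 6720 features, 1710 were left out of the planned tests as absent from the authors' list. Signal over background took the remaining 5010 to 4747, and missing values to 4600. The lowest share of spots above background on an array was 44.7% in Cy5 and 66.5% in Cy3, while on some arrays the share was higher in Cy5.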

Other observations

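The test of features at an extreme level and the test of features raised before treatment had their bounds written before their values were seen, and the other values here were looked at afterwards.

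A hypothesis was that a deleted gene shows as a single feature lowest in both samples of its strain. A feature at least 1 log2 unit below every other sample, with a smaller gap above, was found in 3 of 5 deletion strains: S783 in argR (gap 3.53), S13015 in arcA (2.09) and S4623 in iscR (3.26). A second feature also lay more than 1 log2 unit below every other sample in argR (S1551, 2.05) and arcA (S12823, 1.86), so that only iscR, with a second gap of 0.756, had a single such feature. In norR and metJ the gaps were 0.193 and 0.228. The files do not pair these with names, so whether they are the deleted genes cannot be told.

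Another hypothesis was that the nsrR sample responded weakly because the induced features were already raised before treatment. Of the 61 features called higher with DeaNO in the parent strain, 12 (19.7%, exact binomial 95% interval 10.6 to 31.8) had a Cy3 level in nsrR at least 1 log2 unit above the median of the others, against 15.6% of the other features (Fisher's exact test, two-sided, p = 0.374). This is under the 50% the hypothesis would need, and it passes the bound of 20% set against it by less than the width of that interval. The interval and the test treat features of 1 RNA sample as independent and hold no spread between samples. The Cy3 level of S7687 was 4.59 above that median in nsrR and 2.52 in nsrR_hmpA sample 1.

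The mean of the 2 arrays with exchanged dyes correlated across features at 0.283 with the normal arrays of the same RNA, at 0.606 with parent-strain DeaNO sample 2 and at -0.184 with the control. Across features, the ratios of spots 16 apart in number correlated at 0.295, 32 apart at 0.342 and 64 apart at 0.147, and features are not independent replicates.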
